A study of Homo sapiens with 60 samples.

How the data were processed

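Messenger RNA was sequenced from HepG2 cells, an established line from a human hepatocellular carcinoma, after 24 h with a herbal extract or with DMSO as vehicle. The labels give 60 libraries in 25 groups: 1 vehicle group of 3, and 8 extracts at 500 (High), 100 (Medium) and 20 (Low) µg/mL. Water extracts of Sibjeondaebo-tang (SDT) and Palmul-tang (PMT) are herbal formulas. The 6 other extracts were made with 70% ethanol from single herbs: Poria cocos, Atractylodis Rhizoma, Glycyrrhizae Radix, Panax ginseng, Angelicae Gigantis Radix and Paeoniae Radix. PMT has 2 libraries per dose, Angelica and Paeonia have 1 per dose, and the other extracts have 3. The sample labels give the vehicle as 0.1% DMSO, whereas the series text gives 2%; which is right is not known, and the labels do not give the DMSO content of the treated cultures. The series text also allows lower doses for extracts toxic to the cells, but every treated label carries the 3 doses above. The wortmannin control (10 µM) that the series text mentions was not analysed here. The sample descriptions carry a set code (C1 for vehicle, 8 for the formulas, 9 for Poria and Atractylodis, 10 for Glycyrrhiza and ginseng, 11 for Angelica and Paeonia), so vehicle and each extract never share a code. The titles of all 60 samples, vehicle included, name the same batch (BatchC), and the labels do not say what the set code marks.

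Per the labels' protocols, 1 µg of total RNA with an integrity number above 7 went into an MGIEasy directional mRNA library, sequenced on an MGIseq instrument as 100 bp paired reads. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned with STAR 2.7.3a to GRCh38 (hg38) and counted with RSEM 1.3.3. The values the authors deposited are gene-level expected counts, not normalised: 23.4% of the nonzero values are not whole within a tolerance of 0.005, and the total count differs between libraries. The annotation release and the strand setting are not stated. The table has 60675 genes and 270 columns of samples, of which the 60 columns of these samples were used and the other 210 were not. Gene identifiers were matched to GENCODE release 29 for coordinates on GRCh38 (57055 found) and to a gene name table for symbols (56558 found); 1167 duplicated symbols were replaced by the identifier.

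Expected counts were rounded to whole numbers. Total counts ran from 19057280 to 33233253 per library. Genes were kept by filterByExpr on the groups (16286 of 60675), scaled by TMM, and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of genes come from that test unless another tool is named. One model with a coefficient per group was fitted to the 54 libraries of the 19 groups with 2 or more libraries. Comparisons were High, Medium and Low against vehicle and High against Low for 6 extracts, SDT against PMT at each dose, and the genes called the same way at Low in all 6 extracts. Fold changes of tested genes are on the log2 scale as the edgeR fit gives them, with its default prior count. A prior count of 2 went into log2 CPM, used for principal components, list tests and the ratios of Angelica and Paeonia. Levels are CPM on TMM-scaled library sizes, given with the SD. The common dispersion was 0.00316, a coefficient of variation of 5.6% between replicates. The labels do not say whether replicates are separate cultures; if they are technical, the p-values measure only the spread between these samples. Angelica and Paeonia were compared as log2 ratios to the vehicle mean without any test.

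The tests, the alternatives, the rule for named genes and 32 gene lists were fixed before the data were examined. The lists cover AhR targets, PXR and CAR drug metabolism, the NRF2 antioxidant response, the unfolded protein response, the integrated stress response, cholesterol synthesis and uptake, fatty acid synthesis, PPAR alpha and fatty acid oxidation, bile acid and FXR targets, gluconeogenesis and fasting, hypoxia and glycolysis, mitosis, DNA replication, p53 targets, acute phase proteins, NF-kB and chemokines, metallothioneins and zinc, heat shock, hepatocyte secreted and lineage genes, immediate early genes and MAPK feedback, the interferon response, autophagy and lysosome, TGF-beta with matrix and cytoskeleton, iron and heme, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, and markers of fibroblasts and stellate cells, endothelium, leukocytes and macrophages, and biliary and lung epithelium. Each was tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Overlap of a list with the genes common to all extracts was tested with Fisher's exact test, one-sided, adjusted over all lists and both directions. For lists in Angelica and Paeonia, medians were ranked among 10000 random lists matched on expression in 50 bins.

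Named genes are the 6 largest rises and 6 largest falls of each extract at High against vehicle that also passed in the same direction at High against Low, with every High library on one side of every vehicle library, at least 5 CPM in the higher group, and a symbol that is no clone, intergenic or pseudogene name. From each list with 2 or more members called against vehicle, up to 2 rising and 2 falling genes with the smallest adjusted p were added. For Angelica and Paeonia the 5 highest and 5 lowest ratios at High with at least 10 CPM in the higher of the 2, a symbol under the same rule and a Medium ratio of the same sign and at least 0.5 times as large on the log2 scale were taken, and for the genes common to all extracts the 5 largest mean rises and falls. Other members of the lists are given as examples. Some genes that this rule picked are not reported here.

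The procedure was tested on simulated counts with known changes. In the simulated Poria High vs Low comparison over 16013 genes, 45.8% of genes changed 1.25-fold, 75.5% changed 1.5-fold, 80.0% changed 2-fold and 95.9% changed 4-fold were recovered, with 9 false calls. In the simulated PMT High vs Low comparison over 16002 genes, the shares were 32.7%, 68.8%, 70.0% and 89.6%, with 4 false calls. Each gene had the same spread in all simulated groups, so these values do not cover the wider spread between the real PMT High libraries. Alternatives were DESeq2 1.42.0, its size factors (RLE) in edgeR, no filter on low counts, a fit of only the groups compared, the replicate number as a block, and leaving out each library. Offsets for GC content and transcript length, known for 99.3% of the tested genes, and the mitochondrial share of each library as a covariate in the list tests of High against Low were added after seeing the data.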

Results

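Gene expression was measured in 60 HepG2 libraries to compare the responses to 8 herbal extracts over 3 doses with vehicle. Vehicle, SDT, Poria, Atractylodis, Glycyrrhiza and ginseng had 3 libraries per group, PMT had 2, and Angelica and Paeonia had 1. Vehicle libraries held 27390888 to 29913433 counts and all libraries 19057280 to 33233253. The first principal component of log2 CPM took 18.6% of the variance, and Glycyrrhiza High lay at its end. The second took 8.4%, with Poria High at one end and vehicle at the other. Transcripts of the mitochondrial genome made up 13.6%, 13.4% and 15.2% of the counts in the vehicle libraries, and between 14.7% and 24.8% in the libraries of the other replicated groups.

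All 6 replicated extracts shared a difference from vehicle that was already present at Low. The same 970 genes rose and the same 1114 fell in all 6 Low vs Vehicle comparisons. DNA replication genes were among those that fell, 12 of 24 measured, with MCM2, MCM3, MCM5, MCM6, MCM7 and PCNA (1.6 expected, adjusted p = 7.94e-07 by Fisher's exact test). Heat shock genes were among those that rose, 8 of 17, including the chaperones HSPH1 and HSPA8 and the near-identical pair HSPA1A and HSPA1B (adjusted p = 7.39e-05). Genes of the hypoxia list also rose in all 6, 7 of 25, with VEGFA, PDK1 and EGLN1 (adjusted p = 0.00621). Cytosolic ribosomal proteins fell in 10 of 30 cases, and nuclear-encoded subunits of oxidative phosphorylation in 9 of 24 (adjusted p = 0.000293 for each). No other list was over-represented among the shared genes. Fisher's test takes the genes of a list as independent. In tests of High against vehicle with an estimated correlation between genes (0.573 for hypoxia, 0.520 for ribosomal proteins, 0.436 for oxidative phosphorylation), these 3 lists passed in no extract (smallest adjusted p = 0.128, 0.421 and 0.312). DNA replication passed in Glycyrrhiza alone and heat shock in all but Glycyrrhiza. The DNA replication median in Glycyrrhiza was -0.18 at Low and -1.61 at High, so that pass does not bear on the fall shared at Low. No test with an estimated correlation was run at Low.

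The shared rises with the largest mean were in weakly expressed genes, among them FSBP (mean log2 2.31, from 0.248 CPM in vehicle), which lies within RAD54B, DNAJB13 (2.13), the readthrough gene CFAP298-TCP10L (2.13), SPDYE2B (2.01), which has near-identical copies, and PRNCR1 (1.93). The largest shared falls were ZACN (mean log2 -4.85, from 1.35 ± 1.65 CPM in vehicle), RMRP (-2.38), RN7SL2 (-2.23), RN7SL1 (-2.01) and the antisense gene SCOC-AS1 (-1.23). RN7SL2, a copy of the signal recognition particle RNA that shares reads with RN7SL1, stood at 20.6 ± 6.94 CPM in vehicle (SD, n = 3) and at 1.67 to 9.58 in the Low groups. The mitochondrially encoded list had 13 of 13 members called higher in SDT High and in PMT High than in vehicle (median log2 0.74 and 0.87, 13 and 13 adjusted over the list alone), with adjusted p = 0.203 and adjusted p = 0.168 with an estimated correlation. It had 12 of 13 called higher in Poria High and 8 each in Atractylodis High and ginseng High (12, 10 and 9 adjusted over the list alone), with adjusted p = 0.363, 0.436 and 0.421 with an estimated correlation. In Glycyrrhiza High 2 of 13 were called higher (1 adjusted over the list alone, median 0.17, adjusted p = 0.434).

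These 6 comparisons use the same 3 vehicle libraries. In 10 simulated runs every library, vehicle included, was drawn with no gene changed, and 0 genes were shared in each. The median comparison there had 0 calls, so 0 shared genes was close to certain. The simulated vehicle carried no difference of its own, so these runs do not show what a deviating vehicle set would give. Independent lists of the observed sizes would share 0.292. The excess over that is not a measure of a shared effect. Part of it may come from the shared vehicle libraries, since 3 cannot be divided into sets of 2. The log2 changes of 2 extracts had a mean correlation across genes of 0.688 (simulated 0.432 to 0.488) and a mean covariance of 0.163 (simulated 0.0360 to 0.0474). Without the library Vehicle 2 the shared set had 1135 genes, and with only the groups compared in each fit 892. The shared genes changed by a median log2 of 0.27 to 0.38 in their own direction at Low and of 0.32 to 0.39 at High. Against vehicle the set code differs along with the treatment, so the 2 cannot be told apart, and High vs Low, which uses no vehicle library, is the comparison that follows dose.

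Dose changed expression most in Glycyrrhiza and Poria. In Glycyrrhiza, 4657 genes rose and 4510 fell from Low to High, and in Poria 3264 rose and 2998 fell. Atractylodis had 553 rises and 493 falls, ginseng 429 and 493, SDT 83 and 90, and PMT 33 and 51. Against vehicle the totals ran closer, with 9979 genes called at High in Glycyrrhiza, 8348 in Poria, 5913 in ginseng, 5580 in SDT, 5516 in Atractylodis and 4765 in PMT. At Medium they were 5672, 6303, 4840, 5851, 4593 and 4829 in that order of extracts, and at Low 4867, 3127, 5450, 5833, 4371 and 5048. The Poria Low count was 1649 without Vehicle 2, 1745 without Poria Low 2 and 1037 with only the groups compared. Atractylodis Low had 2888 without Vehicle 2. PMT had 1908 at High without PMT High 2, 2414 at Medium without PMT Medium 2 and 2736 at Low without PMT Low 3.

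**Figure D1:**
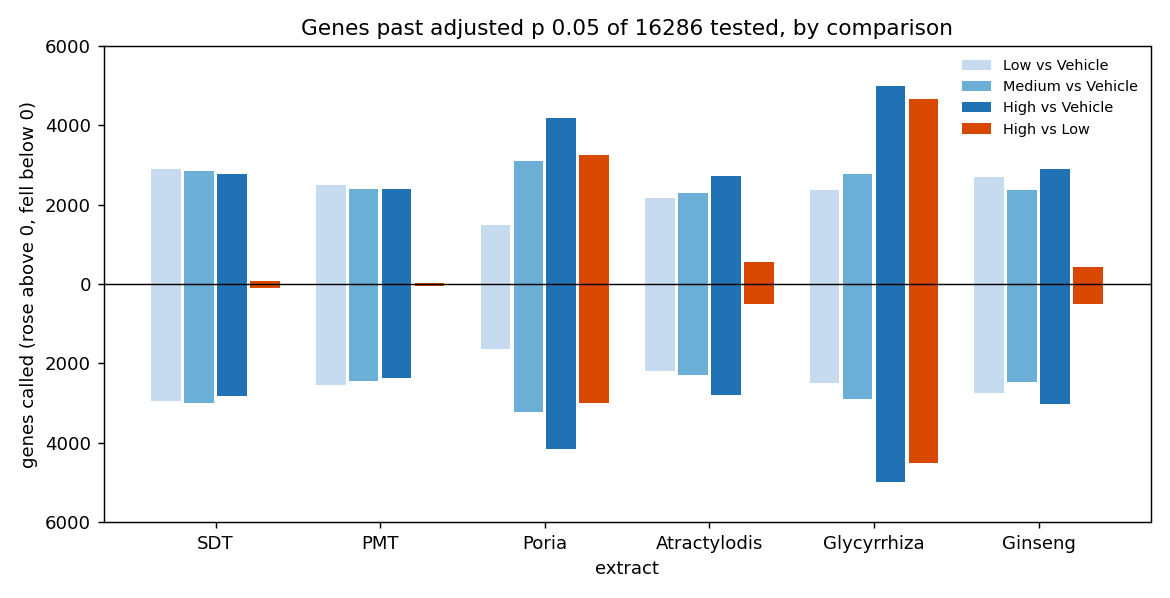
Number of genes past an adjusted p of 0.05 (edgeR quasi-likelihood test), rises above 0 and falls below 0, for 4 comparisons of 6 extracts. High vs Low bars are tall in Glycyrrhiza (4657 rose) and Poria (3264 rose) and short in SDT (83) and PMT (33), whereas bars against vehicle are tall in every extract.

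Glycyrrhiza raised CYP1A1, a xenobiotic-metabolising enzyme induced through the aryl hydrocarbon receptor (AhR), at each dose. Its level went from 11.4 ± 0.816 CPM in vehicle to 37.2 ± 2.44 at Low and 1169 ± 45.3 at High (SD, n = 3), a log2 change of 6.69 (SE 0.12, adjusted p = 3.7e-38) against vehicle and 4.98 (SE 0.11, adjusted p = 5.7e-35) against Low. The gene (ENSG00000140465) lies on chromosome 15 from 74719542 to 74725610. The complement receptor gene C5AR1 rose by a log2 of 5.01 (SE 0.25) against vehicle, to 12.2 ± 1.80 CPM, the monocarboxylate transporter gene SLC16A6 by 4.45 (SE 0.07), the water and glycerol channel gene AQP3 by 3.90, the insulin-like growth factor binding protein gene IGFBP1 by 3.72 (SE 0.27) and LRRC25 by 3.64. IGFBP1, like PFKFB3 and SLC7A11 named below, also rose in all 6 Low vs Vehicle comparisons. Part of their change against vehicle may therefore not follow dose. The Wnt antagonist gene DKK1 (chromosome 10, 52314296 to 52318042) fell from 123.2 ± 6.13 to 5.03 ± 0.535 CPM, a log2 change of -4.62 (SE 0.09, adjusted p = 2.8e-36). UBD changed by -4.19, the amino acid transporter gene SLC6A14 by -4.07, the sodium channel gene SCN1A by -3.62, the kinase gene SGK1 by -3.45 and PCYT1B by -3.35.

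Cell cycle genes fell together between Low and High of Glycyrrhiza. All 24 measured mitosis genes fell (median log2 -1.32, camera adjusted p = 3.9e-27), among them KIF20A at -2 and KIF11 at -1.60, and all 24 DNA replication genes fell (median -1.33, adjusted p = 2.2e-25), among them MCM4 at -1.70 and RRM2 at -1.63; the counts adjusted over the list alone were also 24 and 24. The integrated stress response list had 19 of 20 members higher (median 1.21, adjusted p = 5.67e-15), with DDIT3 at 2.46, ASNS at 2.44 and CTH at 2.19, and ATF5 lower at -0.56. NRF2 targets rose in 22 of 23 cases (median 1.07, adjusted p = 2.29e-18), with the cystine transporter gene SLC7A11 at 2.57, GCLM at 1.97 and NQO1 at 1.25, and PRDX1 fell at -0.25. Autophagy and lysosome genes rose in 19 of 21 cases (median 0.53, adjusted p = 1.16e-10), with SQSTM1 at 1.92 and MAP1LC3B at 1.72. AhR targets rose in 9 of 10 cases (median 1.38, adjusted p = 5.41e-06), including CYP1A2 at 4.69 and CYP1B1 at 3.32, and PXR and CAR targets in 7 of 10 (median 0.46, adjusted p = 0.00151), including CYP3A5 at 1.00, a gene with close paralogs. Adjusted over the list alone, these 5 lists had the same counts.

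Heat shock genes fell in 16 of 17 cases from Low to High of Glycyrrhiza (16 adjusted over the list alone, median -0.39, adjusted p = 2.09e-05), with HSP90AA1 at -0.76, and DNAJB4 rose at 0.69. In the TGF-beta list 10 of 15 fell and 3 rose (11 and 3 adjusted over the list alone, median -0.32, adjusted p = 0.00174), with CCN2 at -1.90. Of 25 hypoxia and glycolysis genes 20 fell, such as LDHA at -1.19, and 2 rose (the same adjusted over the list alone, adjusted p = 4.03e-05), but adjusted p = 0.445 with an estimated correlation. Gluconeogenesis genes rose in 6 of 10 cases, with G6PC1 at 2.77 and PCK2 at 1.57 (6 adjusted over the list alone, adjusted p = 0.00203), and adjusted p = 0.204 with an estimated correlation. In the NF-kB list 8 of 13 fell, with TNFAIP3 at -1.39, and 2 rose (8 and 3 adjusted over the list alone, adjusted p = 0.00591), with adjusted p = 0.0722 with an estimated correlation. CYP7A1, the rate-limiting enzyme of bile acid synthesis, changed by -2.18, and the iron hormone gene HAMP by 1.93.

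Poria raised IGFBP3 from 0.907 ± 0.19 to 9.94 ± 4.00 CPM at High (SD, n = 3; log2 3.46, SE 0.28, adjusted p = 4.2e-14) and the aldo-keto reductase gene AKR1B10 from 41.1 ± 0.596 to 258.1 ± 5.92 CPM. AKR1B10 (chromosome 7, 134527592 to 134541408) changed by a log2 of 2.7 from Low to High (SE 0.07, adjusted p = 7.9e-31). This rise was not particular to Poria, as the Glycyrrhiza High libraries held 242.1 to 258.6 CPM of AKR1B10. In Poria, the transcription factor gene EGR1 rose by 2.57 against vehicle, PFKFB3 by 2.56 and IGFBP1 by 2.5. PFKFB3 and IGFBP1 are among the genes that rose in all 6 extracts at Low. HAMP fell by 3.17 on the log2 scale against vehicle (SE 0.22). The metallothionein genes MT1F and MT1G, which share sequence with their paralogs, changed by -2.96 and -2.30, CLDN19 by -2.10, EXOC3L4 by -2.04 and UPK3A by -1.92. MT1F was already at a log2 of -2.86 against vehicle at Medium.

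Immediate early and MAPK feedback genes rose from Low to High of Poria in 18 of 23 cases (21 adjusted over the list alone, median 0.93, adjusted p = 2.99e-15), with EGR1 at 2.75 and SPRY4 at 1.59. NRF2 targets rose in 19 of 23 and fell in 1 (20 and 1 adjusted over the list alone, median 0.75, adjusted p = 3.17e-20), with GCLM at 1.34 and GCLC at 1.22. Autophagy and lysosome genes rose in 13 of 21 and fell in 2 (13 and 2 adjusted over the list alone, adjusted p = 5.84e-05), with SQSTM1 at 1.64. NF-kB genes rose in 9 of 13 and fell in 1 (9 and 1 adjusted over the list alone, median 0.57, adjusted p = 0.000407), with CCL20 at 1.15, and AhR targets rose in 5 of 10 (5 adjusted over the list alone, adjusted p = 0.00698), with CYP1A1 at 1.85. With an estimated correlation and the mitochondrial share as a covariate, the AhR list did not pass in camera (adjusted p = 0.0711). Mitosis genes fell in 22 of 24 cases (23 adjusted over the list alone, median -0.38, adjusted p = 2.7e-14), with BIRC5 at -0.61. Metallothioneins fell in 6 of 8 (6 adjusted over the list alone, median -1.28, adjusted p = 5.09e-07), fatty acid synthesis genes in 9 of 16 with 1 rise (9 and 1 adjusted over the list alone, adjusted p = 4.62e-06; GPAM at -1.13), and acute phase genes in 8 of 16 (8 adjusted over the list alone, adjusted p = 1.04e-05; FGA at -0.83).

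Several further lists passed in Poria High vs Low with the preset correlation alone. Hypoxia genes rose in 19 of 25 cases (21 adjusted over the list alone, median 0.46, adjusted p = 4.77e-08), with adjusted p = 0.247 with an estimated correlation. Cholesterol genes fell in 15 of 23 with 1 rise (15 and 1 adjusted over the list alone, adjusted p = 1.17e-05), with adjusted p = 0.122 with an estimated correlation. DNA replication genes fell in 16 of 24 with 2 rises (17 and 2 adjusted over the list alone, adjusted p = 0.000587), with adjusted p = 0.278 with an estimated correlation. The unfolded protein response list had 11 of 18 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.00151), with adjusted p = 0.224 with an estimated correlation. In the p53 list 12 of 20 fell and 3 rose (the same adjusted over the list alone, adjusted p = 0.00855), with adjusted p = 0.277 with an estimated correlation. Mitochondrially encoded genes rose in 11 of 13 (11 adjusted over the list alone, adjusted p = 0.00866), with adjusted p = 0.517 with an estimated correlation; the mitochondrial share of the Poria libraries was 15.8% to 17.5% at Low and 19.7% to 22.3% at High.

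**Figure D2:**
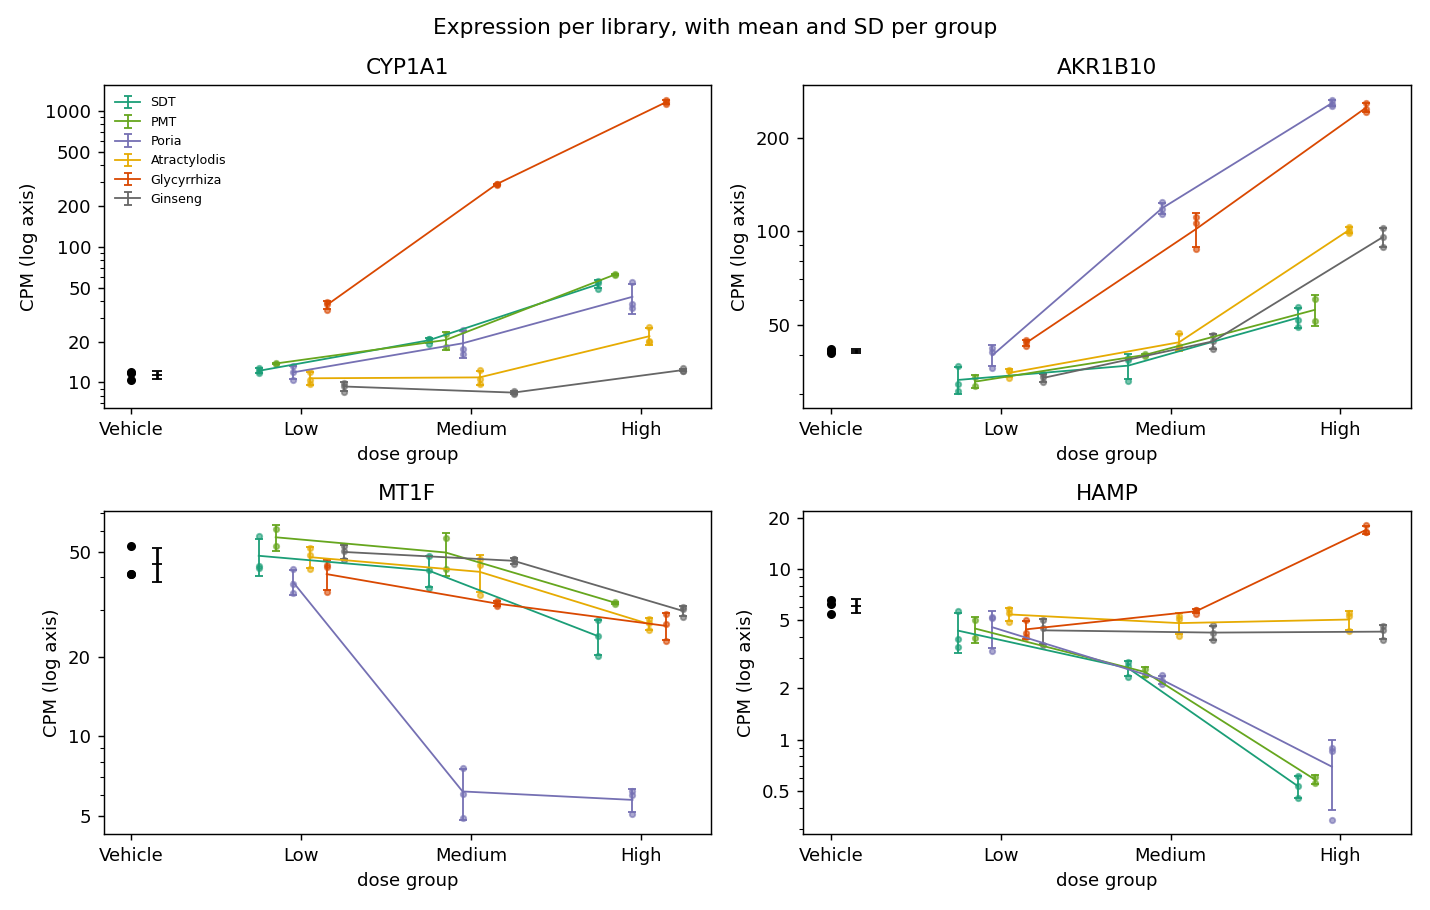
CPM on a log axis of 4 genes in each library of the vehicle and of 6 extracts by dose, with lines through the group means and bars of 1 SD. CYP1A1 reached 1169 CPM in Glycyrrhiza High. AKR1B10 reached 258.1 CPM in Poria High and 242.1 to 258.6 CPM in the Glycyrrhiza High libraries. MT1F fell to 5.75 CPM and HAMP to 0.696 CPM in Poria High. HAMP was as low in SDT High (0.454 to 0.616 CPM) and PMT High (0.560 to 0.610 CPM).

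Atractylodis raised AKR1B10 from 35.0 ± 1.09 CPM at Low to 100.7 ± 2.28 at High (SD, n = 3; log2 1.53, SE 0.07, adjusted p = 2e-20). Against vehicle AKR1B10 rose by a log2 of 1.29 (SE 0.07), the arginase gene ARG1 by 1.15, AKR1C2, which has close paralogs, by 1.01, SULT1A3, which has a near-identical copy, by 1.00, CYP1A1 by 0.95 and SLC7A11 by 0.92. EXOC3L4 changed by -0.99, UPK3A by -0.94, ARSI by -0.93, KAZALD1 by -0.89, ACOT1 by -0.86 and BORCS6 by -0.85. NRF2 targets rose from Low to High in 18 of 23 cases (19 adjusted over the list alone, median 0.39, adjusted p = 3.05e-46), with GCLM at 0.68 and NQO1 at 0.62. Cholesterol genes fell in 15 of 23 (20 adjusted over the list alone, median -0.19, adjusted p = 7.79e-18), with LSS at -0.36 and HMGCS1 at -0.26, and metallothioneins in 7 of 8 (7 adjusted over the list alone, median -0.54, adjusted p = 3.73e-10). Heat shock genes rose in 7 of 17 (8 adjusted over the list alone, adjusted p = 2.79e-06), with HSPA8 at 0.24.

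Fatty acid synthesis genes fell in 6 of 16 cases in Atractylodis with 1 rise (8 and 2 adjusted over the list alone, adjusted p = 4.56e-05), led by ACSS2 at -0.39. TGF-beta genes fell in 4 of 15 (5 adjusted over the list alone, adjusted p = 0.00159), with CCN2 at -0.35, and the interferon list passed with 1 of 16 members called lower (1 adjusted over the list alone, median -0.18, adjusted p = 0.00879). PXR and CAR targets had 2 of 10 higher and 1 lower (2 and 2 adjusted over the list alone, adjusted p = 0.0281), with UGT1A1, whose locus overlaps its relatives, at 0.65. The hepatocyte list (1 rose and 4 fell of 24, adjusted p = 0.0145) had adjusted p = 0.298 with an estimated correlation, the acute phase list (1 rose and 2 fell of 16, adjusted p = 0.0181) adjusted p = 0.179 with an estimated correlation, and the AhR list (2 rose of 10, adjusted p = 0.0221) adjusted p = 0.0574 with an estimated correlation. Adjusted over the list alone, these 3 lists had 1 and 5, 2 and 7, and 2 and 0. The 1046 genes called became 591 without Atractylodis Low 3 and 338 in a fit of only the groups compared.

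Ginseng moved many of the same lists. AKR1B10 went from 33.7 ± 1.03 CPM at Low to 95.7 ± 6.60 at High (SD, n = 3; log2 1.51, SE 0.07, adjusted p = 2e-20). Against vehicle AKR1B10 rose by a log2 of 1.22 (SE 0.07), SULT1A3 by 1.02, the paralogs AKR1C2 and AKR1C1 by 0.96 and 0.90, SPP1, which encodes osteopontin, by 0.86 and SLC7A11 by 0.83. ACOT1 changed by -0.98, MMP11 and RMI2 by -0.75, TMPRSS2 by -0.74 and PGAP3 by -0.72. G6PC1, the glucose-releasing phosphatase of gluconeogenesis, changed by -0.80 against vehicle and by -1.08 against Low (SE 0.15, adjusted p = 2.2e-06). NRF2 targets rose from Low to High in 19 of 23 cases (20 adjusted over the list alone, median 0.34, adjusted p = 8.67e-49), cholesterol genes fell in 14 of 23 (21 adjusted over the list alone, median -0.19, adjusted p = 5.28e-21) and fatty acid synthesis genes in 9 of 16 (12 adjusted over the list alone, median -0.19, adjusted p = 1.8e-19). Examples are PIR at 0.70, LSS at -0.34 and ACSS2 at -0.50.

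Heat shock genes rose in 6 of 17 cases in ginseng (9 adjusted over the list alone, adjusted p = 4.74e-07), metallothioneins fell in 6 of 8 (7 adjusted over the list alone, median -0.40, adjusted p = 8.09e-07) and acute phase genes in 5 of 16 (6 adjusted over the list alone, adjusted p = 0.000187), such as CFB at -0.36. The hepatocyte list had 4 of 24 lower (7 adjusted over the list alone, adjusted p = 9.86e-06), with adjusted p = 0.0515 with an estimated correlation. Other lists passed with the preset correlation and few called members: mitosis (2 rose, adjusted p = 0.134 with an estimated correlation), immediate early genes (4 rose; 0.318), gluconeogenesis (1 fell; 0.320), hypoxia (0 called; 0.662), autophagy (3 rose and 2 fell; 0.134), TGF-beta (2 fell; 0.109), AhR (1 rose; 0.0780) and fibroblast markers (0 of 3 called; 0.0780), each value in brackets being the adjusted p with an estimated correlation. Adjusted over the list alone, mitosis had 2 rises, immediate early genes 7 and 1 fall, gluconeogenesis 3 falls, hypoxia 0 calls, autophagy 4 rises and 2 falls, TGF-beta 5 falls, AhR 2 rises and fibroblast markers 1 fall. The 922 genes called became 525 without Ginseng High 3, 570 without Ginseng Low 1, 594 without Ginseng High 1, 601 without Ginseng Low 2 and 604 without Ginseng Low 3.

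The formulas SDT and PMT changed few genes with dose. In SDT, CYP1A1 went from 12.2 ± 0.494 CPM at Low to 53 ± 3.53 at High (SD, n = 3; log2 2.12, SE 0.12, adjusted p = 1.5e-17), and in PMT from 13.8 ± 0.214 to 62.7 ± 0.759 (SD, n = 2; log2 2.18, SE 0.15, adjusted p = 1.5e-14). HAMP, which encodes the hormone that limits iron export from cells, fell by 3.02 on the log2 scale in SDT (SE 0.24, adjusted p = 2.3e-12) and by 2.93 in PMT (SE 0.29, adjusted p = 5e-09), to 0.535 ± 0.0807 and 0.585 ± 0.0348 CPM; the gene lies on chromosome 19 from 35280716 to 35285143. ID3 and ID1, inhibitors of helix-loop-helix transcription factors, changed by -1.35 and -1.03 in SDT and by -1.34 and -0.78 in PMT. Against vehicle, SDT also raised SLC7A11, SPP1 and MBL2 by a log2 of 0.81 each, AKAP12 by 0.78 and SLC39A10 by 0.77, and lowered LDHD (-1.10) and the paralogs MT1F (-0.91) and MT1X (-0.78). PMT raised SPP1 by 0.93, MBL2 by 0.85, AKAP12 by 0.72 and TGFBR3 by 0.70, and lowered PAQR8 (-0.78), SEMA3B (-0.72) and FURIN (-0.65).

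From Low to High, NRF2 targets rose in 14 of 23 cases in SDT (18 adjusted over the list alone, median 0.21, adjusted p = 1.29e-30) and in 5 of 23 in PMT (19 adjusted over the list alone, median 0.25, adjusted p = 2.24e-23), with GCLM at 0.44 and 0.46. AhR targets had 3 of 10 higher and 1 lower in SDT (5 and 2 adjusted over the list alone, adjusted p = 8.05e-06) and 3 higher in PMT (5 and 1 adjusted over the list alone, adjusted p = 5.83e-06), with ALDH3A1 at 1.85 and 1.5. Metallothioneins fell in 6 of 8 in SDT (7 adjusted over the list alone, median -0.76, adjusted p = 3.91e-20) and 4 of 8 in PMT (7 adjusted over the list alone, median -0.56, adjusted p = 1.48e-12). Fatty acid synthesis genes fell in 6 of 16 in SDT (10 adjusted over the list alone, adjusted p = 7.3e-15) and 3 in PMT (12 adjusted over the list alone, adjusted p = 1.68e-16), with ACSS2 at -0.35 and -0.39. Cholesterol genes fell in 3 of 23 in SDT (14 adjusted over the list alone, adjusted p = 3.39e-13) and in 1 in PMT (6 adjusted over the list alone, adjusted p = 5.59e-12), LSS being called in both at -0.23 and -0.28.

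Other lists passed in the formulas with the preset correlation alone. In SDT these were cytosolic ribosomal proteins (adjusted p = 0.566 with an estimated correlation), nuclear-encoded oxidative phosphorylation (0.566), hypoxia (0.566), mitochondrially encoded genes (0.566), the integrated stress response (0.256) and biliary and lung epithelial markers (0.0702), each with 0 members called, and the hepatocyte list (2 fell; 0.496). In PMT they were acute phase genes (2 fell; adjusted p = 0.112 with an estimated correlation), NF-kB (1 rose; 0.112), TGF-beta (1 fell; 0.0573) and, with 0 called, ribosomal proteins (0.764), oxidative phosphorylation (0.764), hepatocyte genes (0.327) and immediate early genes (0.545). Adjusted over the list alone, SDT had 3 rises in the integrated stress response, 2 among biliary markers, 1 in oxidative phosphorylation and 3 falls among hepatocyte genes, and 0 in the others. PMT had 1 rise and 4 falls among acute phase genes, 1 and 1 in NF-kB, 2 and 2 in TGF-beta, 3 falls among hepatocyte genes, 1 rise among immediate early genes and 0 in the others. Of the genes called in SDT and PMT from Low to High, 23 rose in both (0.2 expected of independent lists) and 31 fell in both (0.3 expected). The 173 genes called in SDT became 91 without SDT High 1, 94 without SDT High 3 and 89 without SDT Low 3, 102 with only the groups compared and 408 with no filter on low counts. The 84 in PMT became 33 without PMT High 2, 45 without PMT High 3, 55 without PMT Low 2, 29 without PMT Low 3, 42 with only the groups compared and 243 with no filter.

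SDT contains the herbs of PMT and others besides, so the pair was compared at each dose. No gene differed at High, Medium or Low by edgeR (0 of 16286 each). At an unadjusted p under 0.05 there were 873, 701 and 802 genes, and the smallest adjusted p were 0.376, 0.217 and 0.262. DESeq2 called 2, 1 and 4 genes, fits of only the groups compared 4, 2 and 0, and fits with no filter on low counts 122, 59 and 80. The genes with symbols that DESeq2 called, chosen after their values were seen, were the metallothionein MT1E at High (log2 -0.45) and DAD1 (-0.35) and NDUFA12 (-0.37) at Low, all lower in SDT, besides AC009086.2 at each dose and the pseudogene RPL21P75 at Low, for which no fold is given. The typical gene's difference at High had an unadjusted 95% interval of 0.19 on the log2 scale to either side. At High 317 genes differed by an absolute log2 over 1 and none was called, so larger differences can also go uncalled after adjustment. The 2 PMT High libraries differed from each other more than any other pair of replicates. Over genes with many counts, their mean squared difference over counting variance was 50.34, against 5.35 in PMT Medium and 10.56 in PMT Low. The next highest pair, in Atractylodis Low, had 29.23. Every comparison with PMT High therefore rests on 2 libraries that disagree.

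With an estimated correlation, 68 of all 384 list tests passed against 158 with the preset one. From Low to High, the NRF2 list passed in all 6 extracts, with adjusted p of 9.59e-07 in SDT, 7.16e-06 in PMT, 2.8e-05 in Poria, 8.51e-09 in Atractylodis, 5.08e-05 in Glycyrrhiza and 4.38e-09 in ginseng. Metallothioneins and fatty acid synthesis passed in all but Glycyrrhiza, cholesterol in SDT, PMT, Atractylodis and ginseng, and AhR in SDT, PMT, Poria and Glycyrrhiza. Mitosis and autophagy passed in Poria and Glycyrrhiza, heat shock in Atractylodis, ginseng and Glycyrrhiza, acute phase in Poria and ginseng, TGF-beta and PXR in Atractylodis and Glycyrrhiza. DNA replication and the integrated stress response passed in Glycyrrhiza, immediate early genes and NF-kB in Poria and interferon genes in Atractylodis. The Poria AhR list no longer passed with the mitochondrial share of the libraries as a covariate, where its median went from 0.43 to 0.20 and its adjusted p from 0.0298 to 0.0711. The Atractylodis PXR list no longer passed with offsets for GC content and transcript length (median 0.04 before and 0.03 after, adjusted p 0.0422 and 0.0811). The other High vs Low lists named here passed under each of these corrections. At High against vehicle, NRF2 passed with an estimated correlation in Poria (0.00199), Atractylodis (0.00287), Glycyrrhiza (0.000265) and ginseng (0.00801), and its median against vehicle at Low lay between -0.16 and -0.01. Heat shock passed at High against vehicle in SDT (0.0485), PMT (0.0219), Poria (0.0361), Atractylodis (0.00117) and ginseng (0.00426), and mitosis in Poria (0.00379) and Glycyrrhiza (3.67e-07). Cholesterol passed in Atractylodis (0.0238) and ginseng (0.0182), fatty acid synthesis in PMT (0.0318), Poria (0.0242) and ginseng (0.0155), and acute phase in Poria (0.0361) and ginseng (0.0421). Metallothioneins (0.0361) and immediate early genes (0.00898) passed in Poria. DNA replication (0.000421), AhR (0.000307), the integrated stress response (0.000307), autophagy (0.000307), PXR (0.00644) and TGF-beta (0.0196) passed in Glycyrrhiza.

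**Figure D3:**
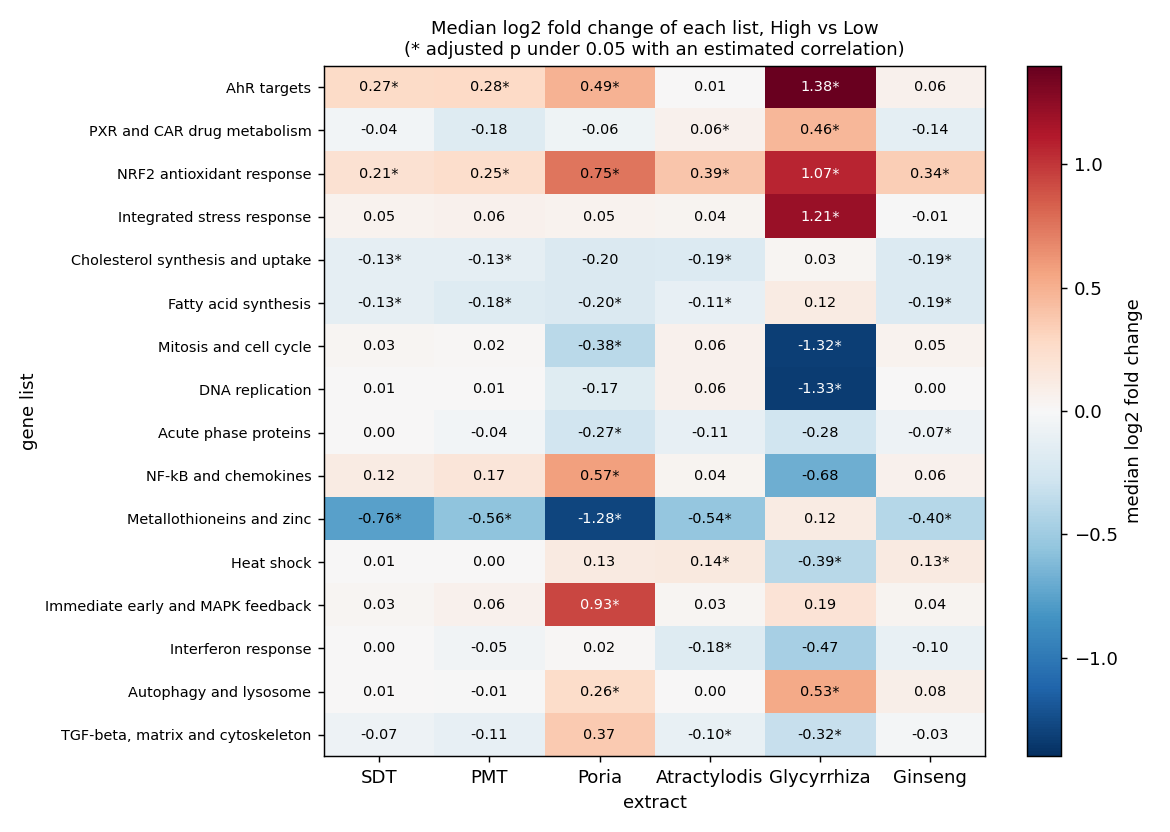
Median log2 fold change from Low to High over the members of the 16 lists that passed in at least 1 extract with an estimated correlation, marked with a star where they passed. NRF2 medians run from 0.21 in SDT to 1.07 in Glycyrrhiza, and metallothionein medians from -1.28 in Poria to 0.12 in Glycyrrhiza.

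Some lists passed in no High vs Low comparison. PPAR alpha genes had 4 rises and 8 falls of 19 in Poria and 6 and 6 in Glycyrrhiza (smallest adjusted p = 0.0920, in ginseng). Bile acid and FXR targets had 3 and 4 of 10 in Poria and 4 and 5 in Glycyrrhiza (smallest adjusted p = 0.0864, in ginseng). Iron and heme genes had 6 and 4 of 14 in Poria and 5 and 5 in Glycyrrhiza (smallest 0.254, in Atractylodis). Replication-dependent histones had 2 and 4 of 12 in Glycyrrhiza (smallest 0.0641, in Atractylodis, where 2 fell). Endothelial markers had 2 rises and 1 fall of 4 in Glycyrrhiza, and leukocyte and macrophage markers 2 rises of 3 in Poria (adjusted p = 0.0936). Adjusted over the list alone, the counts were 4 and 9 for PPAR alpha and 6 and 5 for iron in Poria, 2 and 3 for histones in Glycyrrhiza, and otherwise the same. In lists that passed, median, mean and test had the same sign. In lists that did not, the signs differed in SDT for PXR, gluconeogenesis and DNA replication; in PMT for PPAR alpha, bile acid, gluconeogenesis, autophagy, iron and all 4 marker lists; in Poria for PXR, interferon, iron, ribosomal, histone and biliary lists. They also differed in Atractylodis for PPAR alpha, leukocyte and biliary lists, in Glycyrrhiza for p53, and in ginseng for endothelial and biliary lists.

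High vs Low comparisons of different extracts share no libraries. Atractylodis and ginseng shared 282 rises (14.6 expected of independent lists) and 255 falls (14.9 expected), and the test of the difference called 1 gene. Poria shared 395 rises (110.8 expected) and 331 falls (90.8 expected) with Atractylodis, and 1592 rises (933.3 expected) and 1460 falls (830.2 expected) with Glycyrrhiza. NQO1 and GCLM rose in all 6 extracts, NQO1 by a log2 of 0.41 in SDT, 0.57 in PMT, 1.00 in Poria, 0.62 in Atractylodis, 1.25 in Glycyrrhiza and 0.60 in ginseng.

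Angelica and Paeonia had 1 library per dose, so their values have no replicate check. In Angelica High CYP1A1 stood at 102.1 CPM against 11.4 in vehicle (log2 ratio 3.16, with 2.35 at Medium and 1.62 at Low). PFKFB3 stood at a log2 ratio of 2.51 (2.15 at Low), TMCC1 at 1.56 (1.21 at Low) and TUBB1 at 1.47 (1.33 at Low). EIF3CL, which has a near-identical copy and varied in vehicle (22.3 ± 21.3 CPM), stood at 1.98 with -0.70 at Low. The lowest ratios were RN7SL2 at -2.86 (-1.98 at Low), RN7SL1 at -2.51 (-1.91) and SLX1B, which has a near-identical copy, at -1.87 (-1.25). Next came the antisense gene SLC9A3R1-AS1 at -1.74 (-0.48) and NDUFA1 at -1.25 (-0.57). PFKFB3, RN7SL1, RN7SL2 and NDUFA1 are among the genes shared by all 6 replicated extracts at Low, so their ratios to vehicle are not particular to Angelica or Paeonia. In Paeonia High the highest were PFKFB3 at 3.18 (1.98 at Low), TNS1 at 2.7 (1.29) and CHST15 at 2.58 (1.07), with 113.8 CPM against 19. TUBB1 followed at 2.44 (1.49) and the carbonic anhydrase gene CA9 at 2.38 (0.79). The lowest were RN7SL2 at -3.09 (-3.1 at Low), RN7SL1 at -2.22 (-2.22) and SNHG19 at -1.31 (-1.72). SLX1B followed at -1.29 (-2.41) and HPR, which resembles HP, at -1.09 (-0.57). Among these lowest genes, HPR alone was lower at High than at Low.

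Random lists hold genes that need not move together, and with 1 library per dose a shift of that library can move a whole list. The percentiles given here therefore do not test whether a list changed, and they are rounded. From Low to High, the Angelica AhR list had a median log2 ratio of 0.42 and the NRF2 list 0.28, each at percentile 100 of 10000 random lists. Cholesterol (-0.23), fatty acid synthesis (-0.22), hepatocyte genes (-0.14) and nuclear-encoded oxidative phosphorylation (-0.13) lay at percentile 0. In Paeonia, immediate early genes had a median of 0.91, gluconeogenesis 0.89, hypoxia 0.73, the integrated stress response 0.65, NF-kB 0.42, cholesterol 0.40 and NRF2 0.39, each at percentile 100, and mitosis (-0.55), DNA replication (-0.30), mitochondrially encoded genes (-0.50) and metallothioneins (-1.33) at percentile 0. Against vehicle, the mitochondrially encoded list stood higher in Paeonia High (0.50, percentile 99.9), so its fall from Low to High rests on a high level in the 1 Low library. Of 9011 genes with at least 10 CPM, 31 in Angelica and 204 in Paeonia differed at least 2-fold from vehicle at High, against 27 in a single library of SDT, 37 of PMT, 207 of Poria, 12 of Atractylodis, 588 of Glycyrrhiza and 14 of ginseng.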

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

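The tests with offsets for GC content and length and with the mitochondrial share as a covariate were chosen only after the results were seen. Genes called in opposite directions from Low to High in a pair of extracts, with the difference itself called by the interaction test, were counted for each pair. Glycyrrhiza parted from Poria at 1341 genes (1761.2 expected of independent lists), from Atractylodis at 355 (294.1), from ginseng at 311 (259.8), from SDT at 39 (48.7) and from PMT at 24 (23.7). Poria parted from Atractylodis at 49 genes (200.6) and from ginseng at 45 (177.8). Each of the other pairs had fewer than expected. With SDT, Poria had 3 such genes (NFE2L2, TACC1 and ZNF114), Atractylodis 2 (MTARC1 and ENSG00000273259) and ginseng 2 (ZNF114 and ENSG00000273259). PMT and Poria had 1 (WIPI1), and Atractylodis and ginseng 1 (MYLIP); these genes were chosen after their values were seen.

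HAMP fell in SDT, PMT and Poria and rose in Glycyrrhiza, with differences of the log2 change from Glycyrrhiza of -4.95 (SE 0.27) in SDT, -4.86 (SE 0.31) in PMT and -4.68 (SE 0.26) in Poria. Some lists passed in opposite directions with the preset correlation, and their difference also passed with an estimated correlation, at these adjusted p. Mitosis genes differed between Glycyrrhiza and ginseng (3.31e-08) and between Poria and ginseng (1.89e-06). Heat shock genes differed between Glycyrrhiza and ginseng (0.00423) and between Glycyrrhiza and Atractylodis (0.00524). NF-kB genes differed between Poria and Glycyrrhiza (0.00392) and between PMT and Glycyrrhiza (0.0273). With an estimated correlation, mitosis genes in ginseng (0.134) and NF-kB genes in PMT (0.112) and Glycyrrhiza (0.0722) did not pass by themselves.

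The difference from vehicle common to all 6 extracts at Low is the pattern a user of these data would most want resolved. With offsets for GC content and transcript length, 65.7% of the 2084 genes were still called the same way in all 6 comparisons, which argues against that bias as the whole cause. In 5 of 6 extracts the shared genes moved from Medium to High by less than 0.1 of the change at Low. For those extracts this argues against an effect that grows with dose as the whole cause. In Poria the shared genes moved by 0.16 of the Low change, with medians of 0.27 at Low, 0.33 at Medium and 0.39 at High. The genes were chosen for their change at Low, which can enlarge that change. A difference of the vehicle libraries cancels between Medium and High. A smaller part that grows with dose, and an effect already full at Low, therefore stay open. Low groups of different set codes differed from each other by a median of 11 genes over 12 pairs, which argues against set codes differing whatever the treatment as the whole cause. Some pairs differed more (Poria from Glycyrrhiza by 156 genes, from SDT by 66 and from ginseng by 53). The 3 pairs within a code differed by at most 9. At an unadjusted p under 0.05 by edgeR, pairs of different codes had 538 to 2521 genes and pairs within a code 802 to 1002. No extract has 2 codes, so extract and code cannot be told apart in these pairs. Smaller differences between codes therefore stay open. A difference of the vehicle set alone stays open and cannot be told apart from an effect of any extract, since no treated library carries its code. The labels do not give the DMSO content of the treated cultures, so a difference in DMSO stays open as well.

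The NRF2 list was higher at High than at Low in all 6 extracts. It passed with an estimated correlation in 6 of 6 extracts with the GC content and length offsets, and in 6 of 6 with the mitochondrial share of the libraries as a covariate, which argues against each as the cause. Its median rose from Low to Medium to High in 5 of 6 extracts. The pattern was already High above Low, so only the place of Medium tested a response that grows with dose. Against vehicle the SDT medians were -0.14, -0.14 and 0.08 at Low, Medium and High, and the PMT medians -0.16, -0.08 and 0.11. Part of the rise in these formulas was thus a return from below vehicle. By camera with an estimated correlation, the list did not pass at High against vehicle in SDT (adjusted p = 0.445) or PMT (0.312). It did pass in Poria, Atractylodis, Glycyrrhiza and ginseng. That the extracts may activate NRF2 is a hypothesis found in the same data that tested it. Repeating the doses in cells without NRF2 would test it.

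Mitosis and DNA replication genes fell in Glycyrrhiza High. Their joint median from Low to High was -1.33 with the GC content and length offsets, which argues against that bias as the cause. Of 10000 random lists of like expression 0% had a median as low (lowest -0.33), so genes of like expression did not fall as far. Camera had already set both lists against all other genes, and random lists hold genes that need not move together. The random lists therefore add little of their own. A hypothesis is that the extract may slow division at this dose. Cell number and cell cycle phase were not measured in these libraries, so loss of dividing cells stays open beside slower division. Counts of cells and measurements of DNA content at this dose would tell these apart.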

How the results depend on the processing

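The GC content and length offsets were added after seeing the data; the other alternatives counted here were planned. The mitochondrial share as a covariate, also added later, was run on the High vs Low lists alone and is not among these counts. No named gene at High against vehicle and no list that passed reversed direction. Of 6378 values of named genes at High against vehicle under the alternatives 6138 kept their side of the threshold. Values missing under an alternative were left out of that count. Those genes were picked from the same data for large or clear changes, so most were likely to keep their side. Their changes from Low to High were not counted in this way. Of 1152 values of lists 1057 kept their side. An estimated correlation lowered the list tests that passed from 158 to 68. With no filter on low counts, where 33346 genes were tested, SDT High vs Low had 408 genes (138 shared with the 173; 67.2% rises against 48.0%), PMT High vs Low 243 (74 shared; 60.9% against 39.3%) and SDT vs PMT 122, 59 and 80 at High, Medium and Low. DESeq2 called 2, 1 and 4 in SDT vs PMT. With only the groups compared, which leaves fewer libraries to estimate the spread, Poria Low vs Vehicle had 1037, SDT High vs Low 102, PMT 42, Poria 3977 and Atractylodis 338, SDT vs PMT 4 at High and 2 at Medium, and the shared set 892. The replicate block gave 1 gene (MPV17) in SDT High vs PMT High; replicate numbers were not taken to pair the libraries, as 0 of 20 comparisons with 3 pairs had every paired correlation over 0.1. Atractylodis High vs Low came closest (0.08 to 0.14), and on the fourth principal component its replicate 1 libraries lay at -6.46, -3.73 and -7.4 and the others at 5.91 to 10.01, so a shared replicate effect stays open there; the block gave 1108 genes against 1046.

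Leaving out 1 library removes data by construction, and where PMT keeps 1 sample it is assumed to vary like the other groups. Against vehicle at High, Medium and Low the counts ran from 4389 to 5144, 4542 to 5413 and 4242 to 5568 in SDT, from 1908 to 4449, 2414 to 4526 and 2736 to 4782 in PMT, and from 7470 to 7798, 5136 to 5760 and 1649 to 3699 in Poria. They ran from 4237 to 5051, 3182 to 4218 and 2888 to 4049 in Atractylodis, from 9154 to 9608, 4473 to 5103 and 3507 to 4475 in Glycyrrhiza, and from 4759 to 5505, 3511 to 4456 and 4146 to 5085 in ginseng. High vs Low ran from 89 to 139 in SDT, 29 to 55 in PMT, 5556 to 5894 in Poria, 591 to 951 in Atractylodis, 8490 to 8721 in Glycyrrhiza and 525 to 642 in ginseng. The shared set ran from 1135 to 1954 genes, and SDT vs PMT stayed at 0. The cause of the other moves was not tested. At this depth, the simulated Poria High vs Low comparison recovered 45.8% of 1.25-fold changes, so many small changes go uncalled.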

Other observations

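The predicted test of BMP target genes was written before their values were looked at, but its genes were chosen after HAMP, ID1 and ID3 had been seen. These 3 genes are known targets of BMP and SMAD signalling and fell together in SDT, so a candidate explanation is lower BMP and SMAD signalling. Of 4 other measured targets, 1 was called lower from Low to High in SDT: ID2, at a log2 of -0.61 (SE 0.08, adjusted p = 4.5e-06). SMAD6 was at -0.45 (adjusted p = 0.057), SMAD9 at -0.28 (adjusted p = 0.073) and BAMBI at 0.05 (adjusted p = 0.92). In PMT, ID2 was called as well, at -0.77, and SMAD6 (-0.07, adjusted p = 0.95), SMAD9 (-0.17, adjusted p = 0.66) and BAMBI (-0.18, adjusted p = 0.77) were not. In Poria, where HAMP, ID1 and ID3 also fell, none of the 4 was called (ID2 at -0.19, adjusted p = 0.061). In Glycyrrhiza, ID1, ID3, SMAD6 and SMAD9 were called lower while HAMP and BAMBI (0.50, adjusted p = 3.2e-05) were called higher and ID2 was not called (-0.17, adjusted p = 0.078). These values leave lower BMP signalling in SDT open.

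Other splits of the 6 libraries were counted for 20 comparisons of 3 against 3, and in each 1 of the 10 splits, the real one, gave the most genes. With 10 splits the share cannot go under 0.1. Every other split mixes libraries of both groups, so a difference between the groups from any source, the set code included, favours the real split. In fits of those libraries alone, SDT gave 5569 genes at High (highest other split 1), 5569 at Medium (0), 5521 at Low (0) and 102 from Low to High (1). Poria gave 7461 (0), 5921 (0), 1037 (1) and 3977 (3) in the same order, and Atractylodis 5243 (0), 4362 (0), 3807 (1) and 338 (3). Glycyrrhiza gave 9824 (0), 5950 (0), 5416 (0) and 9348 (0), and ginseng 5913 (0), 5342 (0), 5615 (0) and 909 (2).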
